A study of Mus musculus with 2 samples.

How the data were processed

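FoxO3 occupancy was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in C2C12 cells, a mouse myoblast line that fuses into myotubes when serum is withdrawn. FoxO3 is a forkhead transcription factor restrained by insulin and growth factor signalling. Per the labels, 1 library came from cells at hour -24 relative to differentiation medium (the myoblast sample) and 1 from cells at hour 72 (the myotube sample). Both used the same anti-Foxo3 antibody, and per the labels' protocols the chromatin was sheared by sonication before Illumina paired-end library construction.

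The authors deposited 1 peak list per sample. MACS2 2.1.0 and the mouse build mm9 are named in the submitters' processing notes. The aligner, the control library, the treatment of duplicate reads and the calling threshold are not given in the sources used here. Per the file headers, each list is in the narrowPeak layout. For each peak the authors' caller gave a fold enrichment over its local background (a linear ratio), a −log10 p-value, a −log10 q-value, a score and a summit offset in bp. The deposited score was 10 times the −log10 q-value, cut to a whole number, in 100% of rows. The lowest deposited −log10 q-value was 2.01 in the myoblast list and 2.07 in the myotube list. No read counts accompany the lists, so total depth is unknown. The peak scores are the authors' own. They mainly describe, rank or filter peaks within a list. Where medians, folds at shared sites or counts past a common q-value threshold are set side by side, the lists were called separately and the comparison is descriptive. The test of depth in the closing section also applies a fold taken from the myoblast list to the myotube list.

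The depth behind each peak was recovered in part. A fold enrichment and a p-value together fix a pileup and a background, if the fold is pileup over background and the p-value is the Poisson probability of exceeding that pileup. The whole-number pileup nearest to each deposited pair was taken, with a tolerance of 0.02 on the log10 scale beyond the rounding of the fold. It was found for 501 of 501 myoblast peaks and 45457 of 45457 myotube peaks. On simulated peaks with known pileups, 100% of 2000 were recovered exactly with folds drawn from either list. Simulated peaks whose pileup was not whole passed the tolerance in 8.55% of cases with myoblast folds and 10.05% with myotube folds. The most frequent background, called the floor, was 0.44 reads in the myoblast list and 1.51 reads in the myotube list. A background over 3 times the floor of its list is called raised.

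Peaks were compared by overlap of at least 1 bp. Chance was measured by 1000 random placements of the myoblast peaks on their own chromosomes (bedtools 2.31.1, shuffle), within the span from the first to the last peak of either list, and by 1000 sets in which each peak was moved by 50 to 500 kb. Peaks within 12 kb of each other were joined into clusters, and clusters of 3 or more peaks were counted and set beside 1000 random placements. Peak density used the same spans as chromosome lengths. Shares carry Wilson 95% intervals and counts carry exact Poisson 95% intervals. Both cover counting error only. Planted overlaps (200 of 200) and planted clusters (50 of 50) were found on simulated data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

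With 1 library per group there is no replicate check, and no test of the difference between conditions was made. Regions were named by a rule fixed before the data were examined: the 10 peaks of highest fold in each list, the 5 clusters with the most peaks, and up to 10 shared peaks by myotube fold, from which the text gives examples. The gene table at hand is for another assembly (GRCm38.p6) than the lists, and no mm9 sequence or annotation was used here. Planned comparisons of gene position, distance to transcription start sites, sequence motifs and gene lists were therefore not made, and regions are given by mm9 coordinates, counted from 1. Alternatives were stricter q-value thresholds, autosomes and X only, touching rows merged, other overlap rules, equal list lengths and other joining distances. Removal of peaks with raised background or of the smallest width was chosen after seeing the data.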

Results

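The series compared FoxO3 occupancy between proliferating C2C12 myoblasts (hour -24 relative to differentiation medium) and myotubes (hour 72), and its title places the question in super-enhancer activity during muscle differentiation. Each condition was represented by 1 ChIP-seq library and 1 list of peaks on mm9, so no value below carries a replicate error. The reads behind a peak were few in the myoblast list. The median recovered pileup at a myoblast summit was 8 reads (quartiles 8 and 10) over a median background of 0.44 reads. At a myotube summit the median was 18 reads (quartiles 14 and 25) over a median background of 2.07 reads.

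FoxO3 peaks were far more numerous in the myotube library. The myoblast list held 501 peaks (95% Poisson interval 458 to 547) and the myotube list 45457 (45040 to 45877), a ratio of 90.7. The ratio was larger at stricter q-value thresholds. At a −log10 q-value of at least 5 the lists held 163 and 37541 peaks, a ratio of 230.3. At 10 or more they held 43 and 18815, a ratio of 438. A common q-value asks for a higher fold where background is lower, so these ratios do not compare like folds. Near floor background, a myoblast peak of fold 31.55 (14 reads) had a −log10 q-value of 12.04, and a myotube peak of fold 11.6 (18 reads) had 10.94. Without raised background, the myotube list held 7648 peaks at a fold of 13.52 or more. The myoblast list held 451 without raised background, at any fold. The Poisson intervals cover counting error within each library, and the spread between cultures was not measured.

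**Figure D1:**
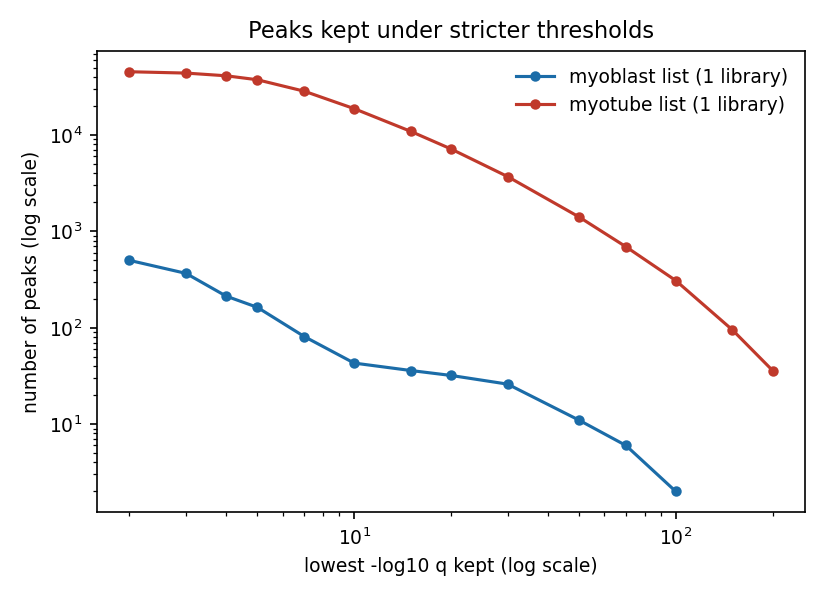
Number of peaks (y axis, log scale) kept at each lowest −log10 q-value (x axis, log scale) in the myoblast list (blue) and the myotube list (red), 1 library each. The myotube curve lies above the myoblast curve throughout, with 18815 against 43 peaks at a −log10 q-value of 10.

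The strongest myotube peak lay on chromosome 19 from 8593461 to 8593821, with a fold enrichment of 165.83 and a recovered pileup of 343 reads. Next by fold were a peak on chromosome X from 100145494 to 100145966 (fold 109.72), a peak on chromosome 19 from 42734134 to 42734928 (fold 105.09) and a peak on chromosome 5 from 66735466 to 66735787 (fold 103.77). Of the 10 myotube peaks of highest fold, the first was the only member that overlapped a myoblast peak. The myoblast peak of highest fold lay on chromosome 3 from 5860363 to 5860665, with a fold of 70.62 and a pileup of 77 reads. It was followed by peaks on chromosome 13 from 113368398 to 113368515 (fold 68.03, 61 reads) and on chromosome 8 from 86280774 to 86280865 (fold 65.34, 29 reads). The 8 myoblast peaks of highest fold all overlapped a myotube peak, as did 2 of the 3 peaks tied at the next fold, 31.55 with 14 reads. The tied peak without an overlap lay on chromosome 8 from 19782603 to 19782682.

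Myoblast peaks were narrow. In the myoblast list 337 of 501 peaks (67.3%, Wilson interval 63.0% to 71.2%) had the smallest width in the list, 76 bp. In the myotube list 5446 of 45457 peaks (11.98%, 11.7% to 12.3%) had that list's smallest width, 122 bp. The median myotube width was 186 bp (quartiles 142 and 257). Median fold enrichment was 18.03 in the myoblast list and 8.59 in the myotube list. The lists were called separately, so widths and folds set side by side between them are descriptive. A smallest width shared by many peaks may be a limit of the calling. At the floor background, the lowest fold in the myoblast list was 13.52.

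Few sites were listed at both times. Of the 501 myoblast peaks, 104 (20.8%, Wilson interval 17.4% to 24.5%) overlapped a myotube peak, and 102 of the 45457 myotube peaks (0.224%, 0.185% to 0.272%) overlapped a myoblast peak. Random placement on the same chromosomes gave a mean of 2.74 overlapping myoblast peaks and at most 11 in 1000 placements. Moving each nuclear myoblast peak by 50 to 500 kb gave a mean of 5.11 and at most 13, against 101 observed. The overlap was therefore above both chance levels, including the one that keeps each peak within 500 kb of its place. The smallest move, 50 kb, exceeds the median gap between myotube peaks (11295 bp), so closer context was not kept. The overlap depended on the rule. With summits within 200 bp it was 105 myoblast peaks (21.0%), and 37 (7.39%) shared at least 50% of both peaks. The 50% rule excludes narrow myoblast peaks inside much wider myotube peaks, whatever their position.

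The shared sites were of different kinds. Of the 43 myoblast peaks with a −log10 q-value of at least 10, 41 (95.3%, 84.5% to 98.7%) overlapped a myotube peak, against 63 of 458 weaker peaks (13.8%, 10.9% to 17.2%). Background was raised at 30 of those 41 shared peaks, in both lists. They included peaks in the regions on chromosome 17 from 39979963 to 39985751, on chromosome 2 from 98502694 to 98507455 and on chromosome 9 from 3000368 to 3002174, where the median myoblast background was 26.0, 150.5 and 79.9 reads. With peaks of raised background left out of both lists, 57 of 451 myoblast peaks (12.6%, 9.88% to 16.0%) overlapped a myotube peak. Among shared peaks with the highest myotube fold, the site on chromosome 19 at 8593461 had a myoblast fold of 15.61 and 14 reads. The site on chromosome 3 from 5860321 to 5860702 went the other way in fold, with 41.67 in myotubes and 70.62 in myoblasts. Its pileup was 184 reads over a background of 4.42 in myotubes, against 77 reads over 1.09 in myoblasts. These counts are not scaled for depth. Their ratio was 2.39, where the floor backgrounds of the lists differed by 3.43 times, or 2.14 times after division by the ratio of smallest widths. The site on chromosome 14 from 75219947 to 75220532 had a fold of 87.02 in myotubes (135 reads) and 22.53 in myoblasts (10 reads), and the site on chromosome 11 from 115138441 to 115138783 had 32.88 (85 reads) and 14.67 (8 reads).

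**Figure D2:**
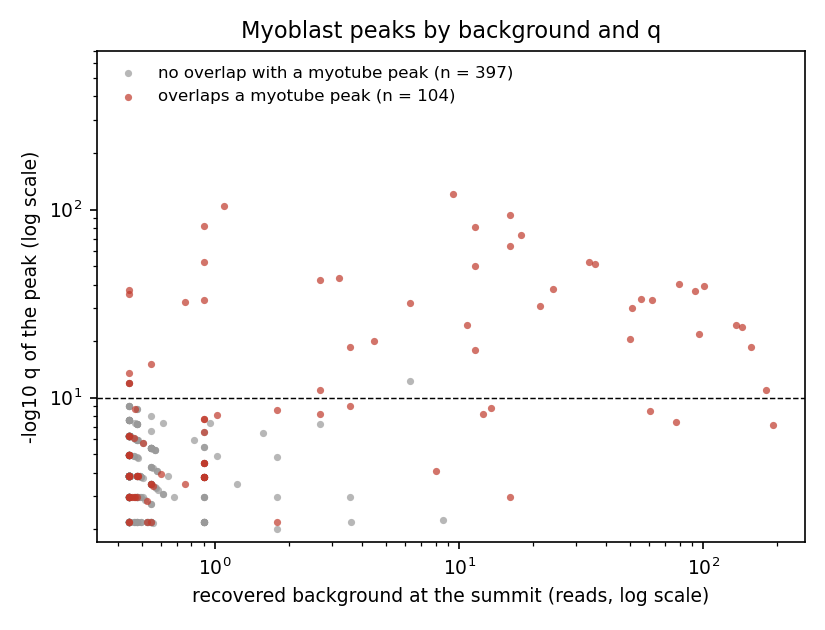
Each point is 1 of the 501 myoblast peaks, by recovered background at the summit in reads (x axis, log scale) and −log10 q-value (y axis, log scale). Red points (104) overlap a myotube peak, grey points (397) do not, and the dashed line marks a −log10 q-value of 10, above which 41 of 43 peaks are red.

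Myotube peaks were grouped along the chromosomes. Joined at 12 kb, 22951 of the 45457 myotube peaks (50.5%, Wilson interval 50.03% to 50.9%) fell into 4026 clusters of 3 or more, whereas random placement gave a mean of 1578 such clusters (1461 to 1698) holding 11.4% of peaks. There were 107 clusters of 20 or more peaks, holding 4504 peaks, and no random placement gave a cluster of that size. These values moved with the settings: joining at 5 kb put 30.7% of peaks into clusters of 3 or more, joining at 25 kb gave 191 clusters of 20 or more (7018 peaks), and a −log10 q-value of at least 5 gave 62 (2407 peaks). The myoblast list had 5 clusters of 3 or more, holding 17 peaks, against a mean of 0.977 and at most 2 under random placement. These were the regions named above on chromosomes 17, 2 and 9, a further region on chromosome 9 from 3020488 to 3032513, and the mitochondrial genome. The mitochondrial span, from 15 to 16286, is little longer than the joining distance, so its 3 peaks join almost wherever they are placed. The random clusters held a mean of 0.585% of peaks, and the 3 mitochondrial peaks are 0.599% of the list. The mitochondrial cluster is therefore no excess over random placement, and the comparison bears on the nuclear regions. Without peaks of raised background the myoblast list had 0 clusters, where 0 of 451 peaks lay in a cluster and the Wilson interval reached 0.845%.

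The myotube clusters with the most peaks lay on chromosome 2 from 76539614 to 76822801 (198 peaks over 283 kb) and from 51990079 to 52206953 (181 peaks over 217 kb). They were followed by regions on chromosome 4 from 32743885 to 32865054 (146 peaks over 121 kb), on chromosome 4 from 123017557 to 123193903 (98 peaks) and on chromosome 11 from 23264317 to 23405108 (96 peaks). They were not compared with gene or exon positions, so whether they are the bodies of long genes with many exons, and whether their peaks lie in exons, was not examined. Peaks in clusters of 20 or more were of modest fold, with a median of 7.93 (quartiles 6.61 and 9.55), against 9.02 (7.09 and 11.9) for isolated peaks. Only 23 of the 4504 (0.511%) reached a fold of 20, against 833 of 13876 isolated peaks (6.003%).

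**Figure D3:**
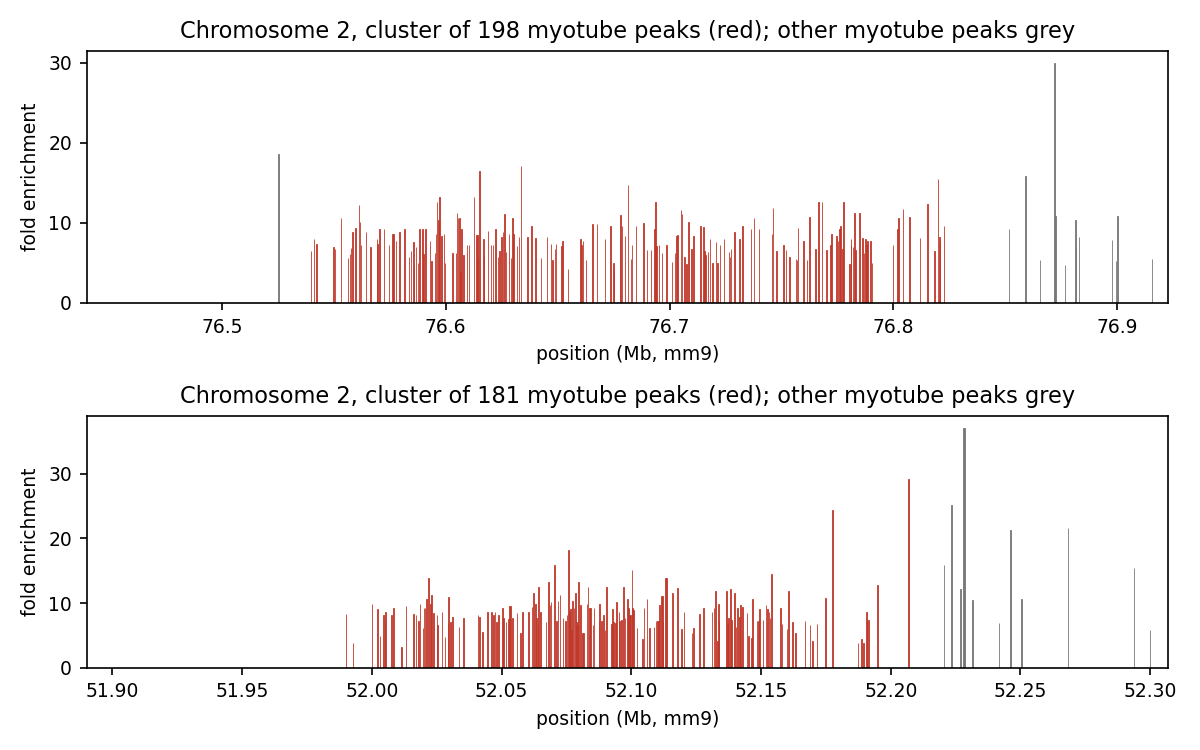
Myotube peaks in the clusters of 198 (top) and 181 peaks (bottom), with 100 kb on either side. Each bar spans a peak on mm9 (x axis, Mb, outlines slightly widened for visibility) and its height is the authors' fold enrichment (y axis). Bars of the cluster are red and other peaks grey. The highest fold is 17.07 in the top cluster and 29.26 in the bottom one.

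Peak density differed between chromosomes in a similar order in both lists. Chromosome 11 had the highest density in each, at 27.8 myotube peaks per Mb (1.57 times the list mean, Poisson interval 1.52 to 1.62) and 0.447 myoblast peaks per Mb (2.30 times, 1.72 to 3.01). Chromosome X was at 0.270 times the mean in the myotube list (0.252 to 0.290) and 0.351 times in the myoblast list (0.175 to 0.627). At a −log10 q-value of at least 5 it was at 0.261 times in the myotube list (0.241 to 0.282). In the myoblast list it was then at 0.496 times (0.161 to 1.16), from 5 peaks, an interval that includes the list mean. Chromosome 7 was at 0.699 times the mean in the myotube list (0.667 to 0.731) and 0.172 times in the myoblast list (0.0559 to 0.402), from 1852 and 5 peaks. Across the 20 chromosomes the relative densities correlated with Pearson r = 0.85 and Spearman rho = 0.92. Each had a two-sided permutation p of 2.0e-05 from 100000 pairings, the smallest they can give, and a Benjamini-Hochberg value of 2.0e-05 over these 2 relations. Without chromosomes X and 11, the farthest from the median, Pearson r was 0.85. Chromosomes are not replicates of a condition. Neither list had a peak on chromosome Y (0 in each), and each had 3 on the mitochondrial genome.

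**Figure D4:**
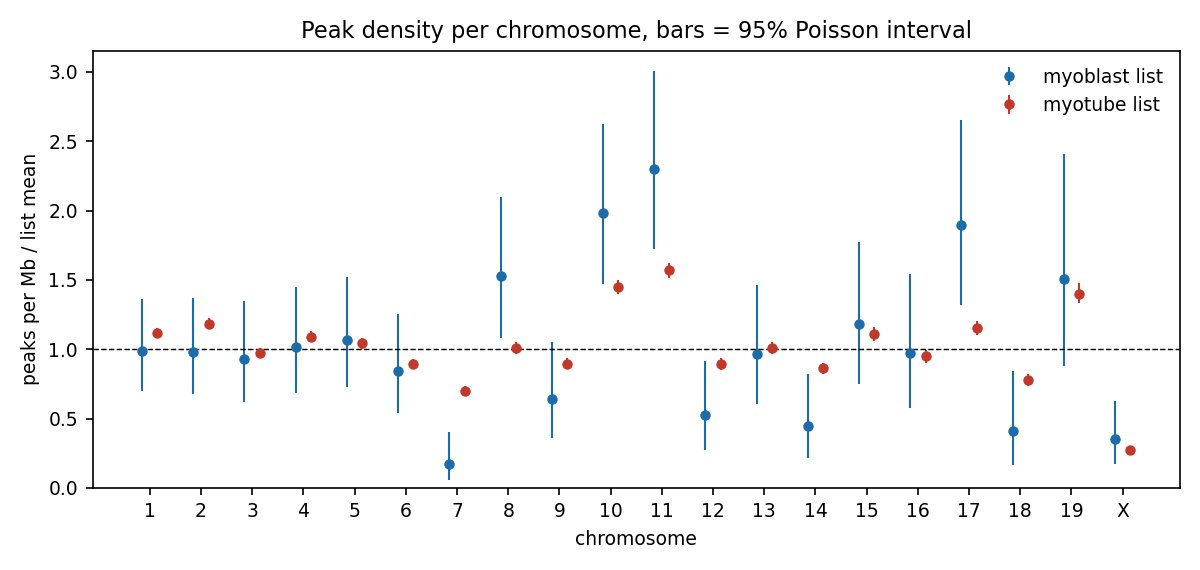
Peaks per Mb on each chromosome divided by the mean of its list (y axis), for the myoblast (blue) and myotube (red) lists, with 95% Poisson intervals as bars. The dashed line marks the list mean. Chromosome 11 is highest in both lists, at 2.30 and 1.57, and chromosome X lies at 0.351 and 0.270.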

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

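No sample was replicated, so every value rests on 1 library per condition, and the low pileup of the myoblast peaks limits what that list can show. The myotube list was longer under every threshold run, by 230.3 times at a −log10 q-value of at least 5 (163 myoblast peaks) and 438 times at 10 (43 and 18815 peaks). As said above, a common q-value does not compare like folds. The share of myoblast peaks matched to a myotube peak was 21.0% with summits within 200 bp and 7.39% with 50% of both peaks required. It was 35.0% at a −log10 q-value of at least 5, and 2.79% against the 501 myotube peaks of highest −log10 p. It was 12.6% without raised background and 43.9% without peaks of the smallest width, both chosen after seeing the data. The corresponding shares of myotube peaks were 0.231%, 0.0814%, 0.147%, 2.79%, 0.130% and 0.154%. Joining at 5 kb gave 3 myoblast and 2589 myotube clusters of 3 or more, and leaving out raised background gave 0 myoblast clusters. The 501 top myotube peaks had a median width of 365 bp, fold of 42.87 and −log10 q-value of 108.7. Of 39 alternative values, 18 stayed within the error or 1.5 times of the reported value and 21 moved. The 18 include merging of touching rows, which could change nothing because no rows overlapped. They also include autosomes and X only, which dropped just the 3 mitochondrial peaks of each list. The causes of the moves were not tested, beyond what each filter removes by construction. Other settings for gene position, distance to start sites, motifs and gene lists were not run, for want of an mm9 genome or annotation. No paired analysis was possible because each group has 1 sample.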

Other observations

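Except for the first width comparison in dense clusters, all tests in this part were chosen after the values they bear on had been seen in part.

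The 397 nuclear myoblast peaks without a myotube overlap still lay nearer to myotube peaks than moved copies did. Their median distance to the nearest myotube summit was 10273 bp, against a mean of 18452 bp (lowest 13385) over 1000 sets moved by 50 to 500 kb, and 49.1% lay within 10 kb against a mean of 35.6%. A hypothesis is that part of the myoblast list marks neighbourhoods that are also occupied in myotubes. Accessible or easily sheared chromatin may give the same distances without FoxO3, and was not tested.

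The first pattern weighed is the 90.7-fold difference in list length. Lower depth alone does not account for it: of 1125 myotube peaks at a fold of 27.04 or more without raised background, which is 2 times the lowest fold listed at floor background in the myoblast list, 6 (0.533%, 0.245% to 1.16%) overlapped a myoblast peak. The floor background differed by 3.43 times, or 2.14 times after division by the ratio of the smallest widths. A poorer immunoprecipitation of the myoblast library cannot be told apart from lower FoxO3 occupancy in myoblasts, because there is 1 library per group. Both stay open. Reads from exons, weighed below for the dense clusters, could also lengthen the myotube list, and this was not tested. Clusters of 20 or more held 4504 myotube peaks (9.91% of the list). Peaks outside them were not compared with exons either, so this share sets no bound on such reads.

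The second pattern is the recurrence of the strongest myoblast peaks in the myotube list. Of the 43 myoblast peaks with a −log10 q-value of at least 10, 31 had raised background, and 30 of these (96.8%, Wilson interval 83.8% to 99.4%) overlapped a myotube peak, against 11 of the 12 others (91.7%, 64.6% to 98.5%). These intervals overlap, and as nearly all peaks of both kinds recurred, this comparison could hardly separate them. Over the whole myoblast list, 41 of 50 peaks with raised background overlapped a myotube peak (82.0%, 69.2% to 90.2%). Without it 63 of 451 did (14.0%, 11.1% to 17.5%), but q-values were not matched. Whether raised background, from collapsed repeats for example, accounts for the recurrence stays open at those 30. The 11 lacked it in the myoblast list. In the myotube list it was raised at 113368398 on chromosome 13 (7.76 reads) and at 79451914 on chromosome 12 (5.17 reads). The 11 were picked for lacking raised background in the myoblast list, so they are no test of background under the cut of 3 times the floor. At 5860363 on chromosome 3 background was 1.09 reads in the myoblast list and 4.42 in the myotube list, just under that cut in each. At 86280774 on chromosome 8 it was at the floor in both, at 0.44 and 1.51 reads. Of those 11, 10 could be compared with unshared myotube peaks of like pileup, and their myotube widths lay at a median percentile of 7.46 (range 0.920 to 60.5), in line with narrow stacks of reads at some of them. Constant FoxO3 binding at some of these sites was not tested and stays open.

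The third pattern is the dense clusters of myotube peaks of modest fold. Raised background from a copy number gain or collapsed repeats is argued against, since the median background in clusters of 20 or more was 1.58 reads, near the floor of 1.51. It was 0.766 times that of isolated peaks, but the groups were not matched on pileup (median 14 reads against 19). A peak of fewer reads is listed only at a lower background, which may lower this ratio. Reads from exons, of processed RNA or captured exons, were considered because each region holds many short peaks over a long stretch, as a long gene with many exons would give. The interquartile range of their widths was 1.96 times that of isolated peaks of the same pileup (137 against 70 bp), above the bound of 1.5 set in advance for rejecting this explanation. Adjoining peaks can merge and widen in dense clusters whatever their origin, and for the 1011 cluster peaks at least 1 kb from both neighbours, a comparison added afterwards, the ratio was 1.47, just under that bound. The widths therefore do not decide, and overlap with exons on mm9 was not examined. Some of the densest regions, the 3 largest among them, may be bodies of long genes with many exons, an impression from their coordinates that was not checked against an annotation, and if so their peaks may reflect RNA or exome reads and not FoxO3 binding. Both stay open.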
